A study of Caenorhabditis elegans with 2 samples.

How the data were processed

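Binding of NPAX-4, a paired-domain protein of the nematode Caenorhabditis elegans, was measured by chromatin immunoprecipitation and sequencing in late embryos of a transgenic strain. The strain carried NPAX-4 with a GFP and FLAG tag at its C terminus in an unc-119 mutant background, and an antibody against GFP was used, per the labels. The 2 samples were biological replicates of one condition, collected 4 h after the population was synchronised by bleaching, and chromatin was sheared by sonication, per the labels. No second condition was present, so the comparisons were between the replicates and between sets of regions. The control library was not analysed here.

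The authors deposited 8 lists of regions, with each kind of list on the genome builds ce10 and ce11. One relaxed list was made from the alignments of each replicate with a shared control, and one relaxed list from both replicates together, per the deposited file descriptions. A further list, thresholded on the irreproducible discovery rate (IDR), was derived from those relaxed lists. The aligner, the peak caller, its version and the IDR threshold are not given in the sources used here. Each region carries a signal value that the authors' peak caller gave, with its scale not stated, and this signal was used only to describe, rank or filter regions within a list. The deposited lists also hold a −log10 q value per region, which was read but used in no test, and the offset of the summit from the region's start. Sequencing depth is unknown, because the files give no read counts. Intervals on shares are therefore 95% exact Clopper-Pearson intervals over regions and cover counting error only.

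Analyses used the ce11 lists with the WBcel235 genome and the Ensembl release 115 annotation, which describe the same assembly, and coordinates are 1-based on that build. Symbols absent from that annotation, or carried there by more than 1 gene, were taken from RefSeq. Coordinates were not converted between builds. Reproducible peaks are the IDR-thresholded regions, labelled optimal by the authors, after the strongest of any overlapping regions was kept. The term names that list and does not mean that each peak was found in both replicates. Of the 341 peaks, 9 overlapped no region of replicate 1. The background was the relaxed list of both replicates together, reduced in the same way, without regions that overlap a reproducible peak. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

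Shares of promoter summits (500 bp upstream to 100 bp downstream of a protein-coding 5′ end), of X-linked regions and of summits within 500 bp of a tRNA gene were compared with Fisher's exact test, two-sided, with exact conditional intervals on the odds ratio. The same test was used for the word TCACGC, the core of a paired-domain half-site, in windows of 75 bp on each side of the summit. All distinct words of 6 bases were tested by logistic regression with the GC content of the window as covariate and Benjamini-Hochberg adjustment. Recovery of peaks was set against 100 random placements on the same chromosomes.

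Members of 33 gene lists were fixed before the data were examined, as were the tests and most alternative settings. The 28 coding lists counted genes whose 5′ end was nearest to a summit within 5 kb, against genes nearest to any region. The 5 noncoding lists counted regions within 500 bp of a gene. Fisher's exact test per list was adjusted over all lists with at least 5 background members. The written plan did not spell out whether coding and noncoding lists form 1 family. They were first adjusted separately, and the joint adjustment was adopted as the literal reading after both sets of p-values had been seen, so both are given for the respiration, snoRNA, snRNA, piRNA and microRNA lists. Named genes were the nearest protein-coding genes of the 25 peaks with the highest signal, any Pax gene near a reproducible peak, the 4 members with the highest-signal peak of each list that passed, and npax-4 and unc-119 in any case. The neighbourhoods of npax-4 and unc-119 were set against 1000 random protein-coding genes.

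The statistics were tested on simulated data. With 341 of 11555 random windows taken as peaks, the word test called 0 words when nothing was planted, and it called 3 of 3 words planted in 5% of the peak windows. The simulated peaks were picked at random, so unlike the real ones they had no GC difference from the other windows. The run with nothing planted therefore does not test the adjustment for GC content. With the 3 words planted in 10% and in 20% of them it called 9 and 26 words, so calls include words that were not planted. Fisher's test called 3.2% of 1000 draws with equal shares, and its interval held a true odds ratio of 3 in 95.2% of draws. Alternatives covered unreduced lists, the 170 peaks with the higher signal, each replicate alone, other distances, windows and covariates, and ce10.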

Results

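Late embryos expressing tagged NPAX-4 gave 354 IDR-thresholded regions on ce11, or 341 reproducible peaks after overlapping regions were reduced. The relaxed lists held 19207 regions in replicate 1, 18799 in replicate 2 and 12454 for both replicates together. The 354 regions were the 354 regions of highest signal in the joint list. Signal ranged from 76.4 to 1202 among them, with a median of 115 in the authors' units.

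The first question was whether the replicates gave the same regions. Among the 354 regions of highest signal in replicate 1, 252 (71.2%, interval 66.2 to 75.9%) overlapped one of the 354 highest of replicate 2, against 0.285% for random placements. The overlap was 42.2% for the 1000 highest regions and 27.1% for the 5000 highest. The reproducible peaks were derived from the relaxed lists of these replicates, the joint list included, so their recovery in each replicate is largely set by that selection. In all, 332 of 341 overlapped a region of replicate 1 and 341 of 341 a region of replicate 2. Random placements gave 15.6% and 16.8%. Those relaxed lists are long, and fewer peaks were among the highest-signal regions of a replicate: 288 (84.5%) in replicate 1 and 282 (82.7%) in replicate 2. The peaks missing from replicate 1 numbered 9, and 8 of them were on the mitochondrial genome. Across 6158 matched regions the Spearman correlation of signal was 0.300 and the Pearson correlation of log signal was 0.654. The correlation was across regions, which are not independent replicates. At reproducible peaks alone the Spearman correlation was 0.710 over 332 regions, and it was 0.178 over the 5826 other matched regions. The reproducible peaks were selected on signal in these same replicates, so the higher value is no independent measure of agreement.

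**Figure D1:**
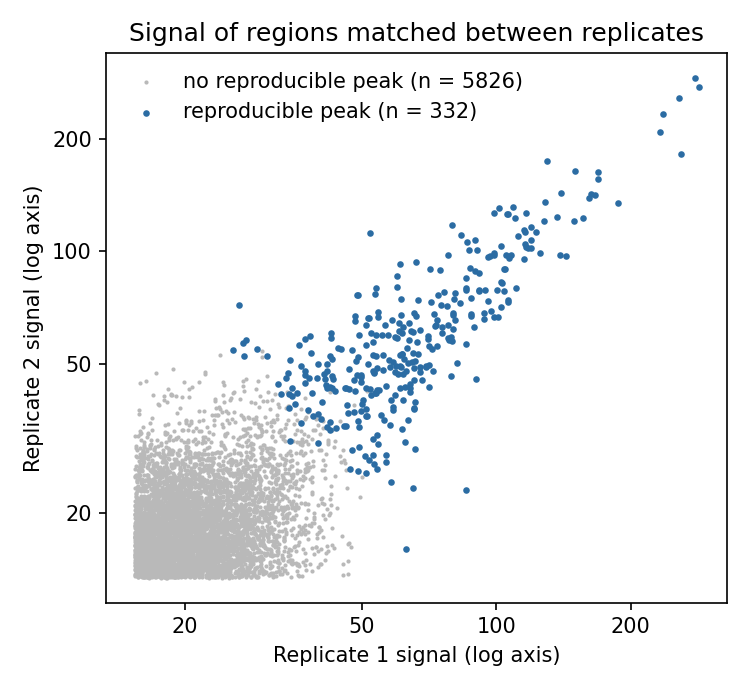
Signal in replicate 1 (x, log axis) and replicate 2 (y, log axis, authors' units) of regions matched between the replicates, with each point a region. The 332 regions at reproducible peaks (blue) lie above most of the 5826 other regions (grey) and were selected on signal in these replicates.

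Many of the strongest regions lay at noncoding genes or on the mitochondrial genome. Of the 25 peaks of highest signal, 5 were mitochondrial, 10 had a small nucleolar RNA (snoRNA) gene within 500 bp, and 3 nuclear peaks had a tRNA gene within that distance. Another 5 nuclear peaks, those near K12H4.5, ears-2, nas-30, idhg-1 and lgc-26, had no annotated noncoding gene within it. The strongest, with signal 1202, lay in the coding sequence of ND5, a subunit of respiratory complex I, at positions 12268 to 12493. Other mitochondrial peaks in this group lay in CYTB, in ND1, in COX3 and in COX1, where the nearest 5′ end was that of COX2, with signals from 299 to 716. All 5 were absent from the list of replicate 1.

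Among the 20 nuclear peaks of this group, the strongest had signal 571 and was intergenic, on chromosome III from 8043810 to 8044139, with its summit at −510 bp from the 5′ end of K12H4.5. The next, with signal 560, lay on chromosome V from 12303473 to 12303792 in an intron of frm-7, beside the snoRNA gene C51F7.4, and its nearest protein-coding 5′ end was that of F55C5.17. Intergenic summits beside snoRNA genes were nearest to W03C9.1 (signal 514), sre-23 (468), str-56 (439), T02E1.2 (315) and cec-4 (273), which encodes a chromodomain protein. Intronic summits beside snoRNA genes lay in pxn-1 (signal 438), cutl-18 (325), Y43F8C.7 (300) and twk-5 (281), a potassium channel gene. Peaks at tRNA genes were nearest to C04A11.5 (signal 328, a leucine tRNA), to F15G9.5 (293, an alanine tRNA in an intron of him-4) and to col-181 (264, a lysine tRNA). The remaining peaks were nearest to ears-2 (signal 311, summit at −11 bp), which encodes a glutamyl-tRNA synthetase, and to nas-30 (306), hrg-5 (298, beside the microRNA gene mir-51), T13C5.6 (279), idhg-1 (272) and lgc-26 (261). All 20 nuclear peaks ranked among the 354 highest regions of each replicate, with lowest ranks of 21 in replicate 1 and 63 in replicate 2.

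Genes for tRNA were near 131 of the 341 reproducible peaks (38.4%, interval 33.2 to 43.8%) and near 181 of 11214 background regions (1.61%, interval 1.39 to 1.86%). The odds ratio was 38 (interval 28.9 to 49.8, Fisher's exact test, two-sided, p = 4.89e-124), and with GC content as covariate in a logistic regression it was 21.1 (interval 16.01 to 27.8). On nuclear chromosomes 125 of 333 peaks were within 500 bp of a tRNA gene, and 79 of these summits lay between the ends of the gene. The median summit was 27 bp from the tRNA 5′ end. Of 612 annotated nuclear tRNA genes, 141 (23%, interval 19.8 to 26.6%) had a reproducible peak. No tRNA product differed from the rest after adjustment (Fisher's exact test, smallest adjusted p = 0.860). Genes whose sequence occurs once in the genome had a peak in 19 of 140 cases (13.6%) and genes with an identical copy in 122 of 472 (25.8%), with an odds ratio of 0.451 (interval 0.251 to 0.774, Fisher's exact test, p = 0.00200). That test took each gene as independent, although 141 genes had a peak and only 125 nuclear peaks were near a tRNA gene. Its interval and p-value may therefore be too narrow and too small.

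**Figure D2:**
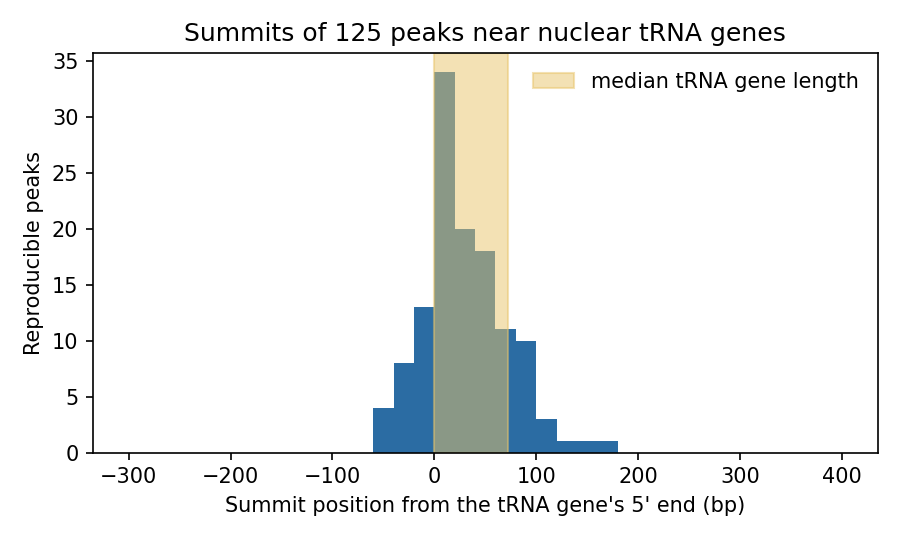
Number of reproducible peaks (y) by summit position in bp from the 5′ end of the nearest nuclear tRNA gene (x) for 125 peaks, with the median gene length of 72 bp shaded. Summits gather within the gene, with a median of 27 bp. A summit at 548 bp lies beyond the plotted range and is not drawn.

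Small nucleolar RNA genes, which guide modification of ribosomal RNA, were near 50 of 341 peaks (14.7%) and near 0.633% of background regions (odds ratio 26.9, interval 18 to 40.02, adjusted p = 6.71e-44 by Fisher's exact test). The snoRNA odds ratio was 46.6 in the 170 peaks with the higher signal and 50.2 without tRNA-associated regions. Small nuclear RNA genes were near 7 peaks (2.05%) against 0.152% of background regions (odds ratio 13.8, interval 4.80 to 35.3, adjusted p = 4.39e-05 by Fisher's exact test). The 4 strongest of these lay at W05B2.8 in an intron of dhc-4, with col-94 as nearest gene (signal 201), and at the spliced leader genes sls-2.4 near egg-5 (164), sls-2.1 near ZK1248.17 (122) and sls-2.2 near ins-13 (115). Genes of piRNAs were near 3 peaks (0.880%) against 3.40% of background regions (odds ratio 0.252, interval 0.0516 to 0.750, adjusted p = 0.0428 by Fisher's exact test). Those peaks were nearest to K02B2.6, Y57G11B.5 and Y57G11C.22. The peaks nearest to K02B2.6 and Y57G11B.5 also had a tRNA gene within 500 bp. In Fisher's exact test the piRNA call was lost without tRNA-associated regions (odds ratio 0.139, adjusted p = 0.101), and the odds ratio was 0.0756 without replicate 2 and 0 in the 170 peaks with the higher signal. MicroRNA genes were near 4 peaks (1.17%) against 0.392% (odds ratio 3.01, adjusted p = 0.280 by Fisher's exact test), and they passed without replicate 1 (odds ratio 4.35, adjusted p = 0.0436). The microRNA odds ratio was 4.90 without tRNA-associated regions, where the list did not pass. Adjusted over the 5 noncoding lists alone, Fisher's exact test gave 1.05e-44 for snoRNA, 6.86e-06 for snRNA, 0.00676 for piRNA and 0.0525 for microRNA genes as adjusted p. With that adjustment on nuclear chromosomes alone, microRNA genes passed (odds ratio 3.09, interval 0.800 to 8.55, adjusted p = 0.0490 by Fisher's exact test). That interval includes 1, so it and the p-value disagree on this result from 4 peaks.

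**Figure D3:**
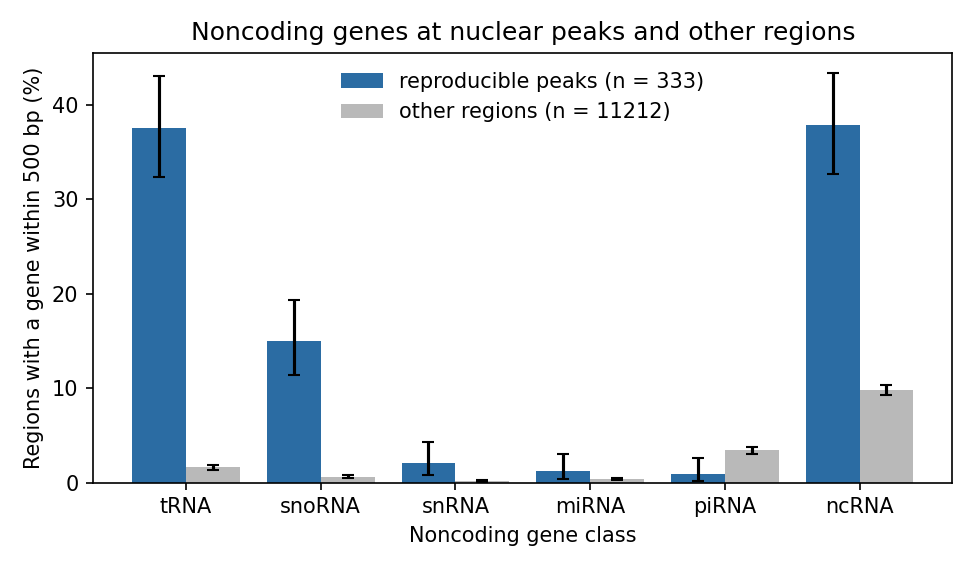
Share of 333 nuclear reproducible peaks (blue) and 11212 nuclear background regions (grey) with a gene of each noncoding class within 500 bp, with 95% exact Clopper-Pearson intervals as error bars. The tRNA share is 37.5% at peaks and 1.60% in the background.

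Promoters of protein-coding genes held 136 of 341 summits (39.9%, interval 34.6 to 45.3%) and 16.4% of background summits (interval 15.7 to 17.1%). The odds ratio was 3.39 (interval 2.69 to 4.25, Fisher's exact test, two-sided, p = 3.20e-24). Of 333 nuclear summits, 219 (65.8%) were intergenic, 31.2% intronic and 2 (0.601%) in coding exons, against 41.6%, 40.8% and 12.4% of background summits. Among the 208 nuclear peaks over 500 bp from a tRNA gene, 55.8% were at a promoter, against 16.5% of such background regions (odds ratio 6.38). Against random positions the odds ratio was 5.08.

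The X chromosome held 77 of 333 nuclear peaks (23.1%, interval 18.7 to 28.0%) and 14.4% of background regions. The odds ratio against the autosomes was 1.79 (interval 1.36 to 2.33, Fisher's exact test, two-sided, p = 2.70e-05). X makes up 17.7% of nuclear chromosome length, more than its share of the background. Against that length the odds ratio was 1.40 (binomial test, p = 0.0117). The tRNA-associated peaks on X numbered 59. Without tRNA-associated regions the direction reversed: 18 of 208 peaks (8.65%) and 14% of background regions were X-linked, with an odds ratio of 0.584 (interval 0.338 to 0.951, Fisher's exact test, p = 0.0258).

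Of the coding lists, nuclear-encoded genes of mitochondrial respiration had 4 of 18 background members near a peak (22.2%) against 4.32% of other genes (odds ratio 6.33, interval 1.51 to 20.3, adjusted p = 0.0428 by Fisher's exact test over 32 lists). The members were nuo-2 (signal 101), cox-6A (96.3), cox-5A (95.5) and cyc-1 (83.4), which encode parts of the electron transport chain. The nuo-2 summit lay in the 3′ UTR of T10E9.14, and a small nuclear RNA gene lay within 500 bp of the cox-6A summit. This call rests on 4 genes. In Fisher's exact test it was lost with adjustment over the 27 coding lists alone (adjusted p = 0.181) and without replicate 2 (odds ratio 5.09, adjusted p = 0.150). It was also lost in the 170 peaks with the higher signal, none of which had a member as nearest gene (odds ratio 0). A peak in an intron of cox-6B (signal 161) was counted for swsn-3, whose 5′ end was nearest. The odds ratio of the list was 10.2 without tRNA-associated regions.

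No other coding list passed against genes near any region. With all protein-coding genes as background, chemoreceptor genes were less often near a peak (odds ratio 0.424, interval 0.192 to 0.818, adjusted p = 0.0397 by Fisher's exact test). Neurotransmitter and neuropeptide genes had 6 of 65 members near a peak, collagen genes 5 of 66, chemoreceptor genes 9 of 275, nuclear hormone receptors 3 of 98 and ribosomal protein genes 3 of 35. Translation factors had 2 of 15 members near a peak and cell cycle and replication genes 2 of 24. One member each had a peak among bHLH factors (1 of 16), aminoacyl-tRNA synthetases (1 of 16), proteasome genes (1 of 10) and histone genes (1 of 13). No member had a peak among homeobox factors (0 of 41), pan-neuronal genes (0 of 23), epidermis genes (0 of 23), body wall muscle genes (0 of 22) and Wnt pathway genes (0 of 16). The same held for innexins (0 of 13), Notch pathway genes (0 of 12), argonaute and small RNA genes (0 of 12), intestine genes (0 of 11) and germline and P granule genes (0 of 9). It held as well for T-box factors, pharynx genes and heat shock genes (0 of 8 each) and for GATA and endoderm factors and glia genes (0 of 7 each). Pax family genes had 0 of 4, too few for a test.

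The word TCACGC or its complement was in 18 of 341 peak windows (5.28%, interval 3.16 to 8.21%) and 2.88% of background windows (odds ratio 1.88, interval 1.09 to 3.07, Fisher's exact test, two-sided, p = 0.0209). Peak windows had a mean GC content of 46% against 36.7%. With GC content and promoter class as covariates the odds ratio was 1.20 (interval 0.723 to 1.98), so no excess beyond base composition was detectable. The call was also lost in the 170 peaks with the higher signal (odds ratio 1.88), without tRNA-associated regions (1.72) and without replicate 1 (1.54). In the search over all distinct 6-base words with GC content as covariate, 194 were more frequent and 134 less frequent at peaks after adjustment. These counts were 113 and 45 in the 170 peaks with the higher signal, 117 and 57 without tRNA-associated regions and 456 and 263 with no covariate. Simulated data with 3 words planted in 20% of peak windows gave 26 called words, so counts of words can exceed the number of distinct motifs. The strongest calls were GTTCGA (33.1% of peak windows against 5.56%, odds ratio 6.42), CGAACC (27.6% against 3.35%) and ACCACT (24.6% against 4.46%). GAACCC, GCGCCA, AACCCG, AGCGTG, TAACCA, CGCAAG and GGCGCA followed. GTTCGA is within the core GGTTCGA of the B box, an internal promoter element of tRNA genes. On the other strand CGAACC is within that core, and GAACCC and AACCCG share bases with it, so these words may mark the same sites.

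The loci carried by the transgene had no reproducible peak within 20 kb. Around random protein-coding genes the median was 0 such peaks and the 95th percentile 1, so this absence is not informative. Near npax-4 on chromosome IV (8877390 to 8879910) there were 4 regions of the joint list, with a highest rank of 1029, and near unc-119 on chromosome III (10902641 to 10908935) there were 9, with a highest rank of 492. Random protein-coding genes had a median of 4 regions and a 95th percentile of 11. In replicate 2 alone unc-119 had 16 regions against a 95th percentile of 15, and 4.7% of random genes had at least as many. Within 10 kb it had 10, against a 95th percentile of 9, and within 40 kb it had 22, below the 95th percentile of 27. In replicate 1 alone it had 11 within 20 kb, against a 95th percentile of 15, and npax-4 was below the 95th percentile in both.

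The ce10 lists gave 366 IDR-thresholded regions, or 353 after reduction, and 82 of the 366 were on X, against 79 of 354 on ce11. The median signal was 114 on ce10 and 115 on ce11, and 349 of the 354 ce11 signal values had a ce10 value within 0.1%.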

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

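Alternatives that set aside tRNA-associated regions, kept nuclear chromosomes or peaks in both replicates' lists, used chromosome length, adjusted the tRNA share for GC content or adjusted coding or noncoding lists alone were chosen after seeing the data. The promoter share (10 alternatives) and the tRNA share (8 alternatives) kept their direction and their side of the threshold throughout, with odds ratios without 1 replicate of 3.47 to 3.51 and of 43.1 to 48.5, and the tRNA odds ratio was 21.1 with GC content as covariate. The X odds ratio was 1.52 to 1.62 without 1 replicate and 1.40 against chromosome length, and it reversed to 0.584 without tRNA-associated regions. The Pax word lost its call in the 170 peaks with the higher signal (odds ratio 1.88, where fewer peaks were tested), without tRNA-associated regions (1.72), with GC content and promoter class as covariates (1.20) and without replicate 1 (range 1.54 to 1.81 without 1 replicate). Passing lists numbered 3 without tRNA-associated regions, where the tRNA list cannot pass and the piRNA call was lost (odds ratio 0.139), and 0 of 27 for coding lists alone, where 1 had an unadjusted p under 0.05 by Fisher's exact test. Noncoding lists alone gave 4 of 5, and 5 of 5 on nuclear chromosomes, with microRNA genes gained by p-value though their interval includes 1. Passing lists numbered 6 without replicate 1, with microRNA genes gained (4.35), and 6 with all protein-coding genes as background, with chemoreceptor genes gained (0.424). The respiration list had an odds ratio of 0 in the 170 peaks with the higher signal, which leaves out its 4 peaks. More frequent words numbered 113 in those peaks, 117 without tRNA-associated regions and 456 with no covariate, and less frequent ones 45, 57 and 263. The number 170 is fixed by construction. The overlap of top regions was 42.2% at 1000 regions and 27.1% at 5000, where the cause was not tested, and the signal correlation was 0.710 at reproducible peaks, which were selected on that signal, and 0.178 elsewhere. The nuclear peaks named for their signal stayed within the 354 highest regions of each replicate, and the 5 mitochondrial ones have no value without replicate 2. No IDR value is given per peak, so a stricter IDR was not run. Depth is unknown, so what it limits was not tested.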

Other observations

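The word search away from tRNA genes and the tests on the internal promoter sequence and on single-copy genes as the whole cause were chosen after the result was seen. At nuclear peaks over 500 bp from a tRNA gene, 9 of the 10 strongest words of all peaks were still more frequent, and CGCAAG, GCGCCA and GGCGCA were again among the 10 strongest. CGCAAG was in 20.2% of 208 windows against 2.99% of the background (odds ratio 5.56 with GC content as covariate), CGCGCA in 25.5% against 4.25% and TTGCAA in 21.2% against 8.16%. The share of peaks near snoRNA genes was highest at the top of the list: 18 of the 50 strongest peaks fell in the snoRNA class (36.0%, interval 22.9 to 50.8%), against 14 of the 191 peaks below rank 150 (7.33%, interval 4.07 to 12%).

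The excess of tRNA genes at reproducible peaks was set against technical explanations. GC content did not account for the whole of it: the odds ratio of 38 became 21.1 with GC content as a covariate, with a lower bound of 16.01. A single replicate is excluded as the source, since the lower of the shares in the replicates' top regions was 35.1%. Reads shared between identical copies may contribute: single-copy genes had a peak 0.525 times as often as multi-copy genes (interval 0.336 to 0.819, with each gene taken as independent). That value does not settle the bound of 0.5 set beforehand. Regions near single-copy genes alone, 14 of 333 nuclear peaks, were still over-represented (odds ratio 16.3, interval 7.93 to 32.2). Identical copies therefore do not account for the whole excess. Single-copy means that the full gene sequence occurs once, so reads shared between nearly identical genes were not tested. A candidate explanation that stays open is RNA polymerase III promoter sequence. The B box core GGTTCGA was also more frequent at peaks over 500 bp from a tRNA gene (odds ratio 3.97 with GC content as covariate, interval 2.23 to 7.06). It was in 15 of 208 windows (7.21%) against 1.21% of the background. Most of these 15 windows lay beside snoRNA genes, including those nearest to F55C5.17, str-56, Y43F8C.7, T27A3.8, M106.8, M04B2.7, F23C8.13 and T24H7.2. Others, such as those nearest to hrg-5 and sms-3, did not. Whether the excess holds away from snoRNA genes was not tested. Whether NPAX-4 or the assay itself marks genes with such promoter sequence was not tested, as no other tagged or untagged strain was analysed here.

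The X excess is consistent with the location of tRNA genes, 45.1% of which are X-linked: without tRNA-associated regions the odds ratio was 0.584 (interval 0.338 to 0.951). The interval lies below 1, where the prediction written beforehand expected it to include 1, and the cause of that deficit was not tested. Genes for tRNA on X and on the autosomes had a peak in 25.4% and 21.1% of cases, with an odds ratio of 1.27 (interval 0.854 to 1.88, Fisher's exact test, p = 0.247). Each gene was taken as independent here too.

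Mitochondrial regions numbered 0 in replicate 1 and 19 in replicate 2. If replicate 1 added no mitochondrial signal, joint signal relative to replicate 2 should be low there. The ratio ranged from 1.05 to 2.11 at 8 mitochondrial peaks, with a median of 1.88, against a median of 2.12 and a 5th percentile of 1.68 at nuclear peaks. Of the 8, 3 lay below that percentile and the others above it, so whether replicate 1 added signal there stays open. Why its list holds no mitochondrial region was not tested, since this ratio would be the same for reads that were filtered out and for reads that were absent. No biological explanation was tested.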
